A study of Mus musculus with 2 samples.

How the data were processed

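Droplet single-cell RNA sequencing was done on FACS-sorted endothelial and hematopoietic cells of mouse liver at postnatal day 15, per the labels, with 1 control and 1 c-Maf KO library. Each pooled 1 male and 1 female mouse. The authors deposited a table of whole UMI counts per gene and cell barcode for each library, with 32285 genes, and 1 annotation table for 15835 cells. FastQC 0.11.3, Cell Ranger 4.0.0, Seurat 3.2.3 and the mm10 build are named in the submitters' processing notes, with no role or order. The parameters of alignment and counting are not given in the sources used here. The labels also name bulk RNA library kits beside the droplet method, and which kit was used is not given in the sources used here.

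The deposited annotation gives the UMI count and gene count of each cell, the percent of mitochondrially encoded UMIs, cell cycle scores with a phase call, a sex call and a cluster name for 23 clusters, per the file headers from a clustering at resolution 0.5. The deposited UMI counts were checked against the tables and equal the sums over genes seen in at least 10 barcodes in 7669 of 7669 control and 8150 of 8166 c-Maf KO cells. The deposited percent of mitochondrial UMIs stays under 20 and the gene count between 200 and 5000 in every annotated cell. All 1369 control and 892 c-Maf KO barcodes without an annotation lie outside these limits. The scale of the deposited scores (S, G2M and embedding coordinates) is not stated, and the scores were not compared. The authors' phase calls placed 4.82% of control and 20.2% of c-Maf KO endothelial cells in S phase and 2.48% and 10.3% in G2 or M. No cycling was read from these calls. The authors' call of a female cell was the same as the presence of an Xist UMI, and 59.2% of control and 61.1% of c-Maf KO cells called male held no UMI of 4 Y-linked genes. Female-type and male-type cells were therefore defined by Xist without Y-linked UMIs and the reverse, as a description of the pooled mice and not as replicates. A type needs a detected UMI, so both types hold few shallow cells and are not all cells of a mouse. Of 363 control endothelial cells under 1128 UMIs, 12 were female-type and 21 male-type. A share over all cells can lie outside both types' shares, as for control Kupffer cells (16.7%, against 6.03% and 11.7%).

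Groups came from the sample labels, and cell types from the authors' annotation. The authors' abbreviations are not explained in the sources used here. S, S2, KOS_1, KOS_2 and KOS_3 were taken as sinusoidal, C-EC as cycling endothelial and PV as large vessel cells, from their names, leading genes and cell type markers fixed before the data were examined. KOS_2 was placed there by its name alone, as its leading genes include 2 megakaryocyte markers, 1 endothelial marker and no sinusoidal marker. The cluster named CMP had leading genes of plasmacytoid dendritic cells, and the one named Mast_cells those of basophils. Clusters D and H, with 122 control and 90 c-Maf KO cells of mixed leading genes, entered no cell type. UMIs were summed over the cells of a type in each library and divided by their total UMIs, in CPM. With 1 library per group no test was possible, and no p-value was computed. Levels carry exact Poisson, shares exact binomial (Clopper-Pearson) and ratios exact conditional binomial 95% intervals. The log2 ratio of c-Maf KO over control used sums with 0.5 UMI added. A gene was called higher or lower by size alone, at 1.5-fold or more with an interval that excludes equality and at least 50 UMIs over both sums. A sum of 0 was set against a floor of 3 counts over the cell type.

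For 33 gene lists fixed before the data were examined, the median log2 ratio of members with at least 20 UMIs was placed as a percentile among 10000 random lists of the same size matched on expression in 20 bins. Percentiles at or below 2.5 or at or above 97.5 were said to stand apart, as a description of these libraries. 6 listed symbols were not in the tables. Named genes followed a rule fixed beforehand. They are Maf, then the 12 genes with the highest and the 12 with the lowest log2 ratio among those with at least 200 UMIs in endothelial cells. Xist, Tsix, Y-linked, predicted, mitochondrial, ribosomal protein, hemoglobin and immunoglobulin genes and members of the 4 lists of other cell types' transcripts were left out of these. Next come up to 3 members per direction of each list with at least 50 UMIs, and in other cell types with at least 50 cells per library the 3 highest and 3 lowest genes. Other named genes were chosen after their values were seen: Slbp, Sftpc, Hpgd and Cyp4b1.

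For shares of cells with a UMI of Mki67 or Top2a, each cell was thinned to 1128 UMIs, the 10th percentile of endothelial cells. Marker lists of lung endothelial, alveolar epithelial and mast cells were written before their sums were taken, after the levels of Foxf1, Sftpc and Mcpt4 had been seen. Scrublet marked 122 control (1.59%) and 189 c-Maf KO cells (2.31%) as doublets. They stayed in the main values and were removed in an alternative.

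Other ways of computing the values, chosen before the data were examined, covered median of ratios and TMM (edgeR 4.0.16, R 4.3.3) scaling, equal weight per cell and thinned cells. They also covered a filter of at least 1000 genes and under 5% mitochondrial UMIs, every endothelial barcode of own clustering, own cell type calls, doublet removal and removal of cells above the 90th percentile for hepatocyte, erythroid or leukocyte transcripts. Female-type and male-type cells alone, the control library's subtype mix, removal of cells with a cycling marker, a pseudocount of 5 and other minimum counts for list members were chosen then as well. Leaving out c-Maf KO cells of S and S2, leaving out KOS_2, and for subtype shares a minimum of 2000 UMIs were added after the data were seen. Own clustering used 2000 variable genes, 30 principal components and 15 neighbours with Leiden clustering (scanpy 1.11.5, leidenalg 0.10.2) at resolutions 1 and 2. Other values came from Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots from matplotlib 3.10.9. Relative to total UMIs, median of ratios scaling shifts every log2 ratio by 0.12 and TMM by 0.10, and the median of all 13288 measured genes was -0.08.

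The size rule was tested on simulated counts drawn from the endothelial sums of 11919 genes. The counts varied by counting error only, so the rates below cover no spread between mice, libraries or cells. Changed genes and list members were drawn from genes with at least 200 UMIs. All 100 genes changed 2-fold and all 100 changed 4-fold were recovered (100%), 0.486% of 11719 unchanged genes were called, and the interval held the true ratio for 95.6%. Of 100 simulated lists of 25 unchanged genes, 8% fell outside the percentiles that stand apart, and 100% of 20 lists changed 2-fold lay above 97.5. Coordinates are from GENCODE M21 on GRCm38, the assembly that mm10 names.

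Endothelial cells held 16238502 control and 22621086 c-Maf KO UMIs, so that 50 UMIs over both sums was the least count at which a gene was called. The explanations weighed at the end were tested by rules written down beforehand, except those named there as chosen after the result was seen. The rule for barcodes shared between the libraries was loosened after its value was seen and then put back as written, and the value is given under the written rule.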

Results

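Gene expression was measured in single cells from the livers of mice at postnatal day 15, sorted by fluorescence-activated cell sorting and captured in droplets. Each transcript molecule carried a unique molecular identifier (UMI), so that counts are molecules and not PCR copies. The control library and the c-Maf KO library each held endothelial and hematopoietic cells pooled from 1 male and 1 female mouse, and each group had 1 library. The sample titles speak of control and c-Maf KO endothelial cell mice, which was read as a deletion in endothelial cells. The driver of the deletion is not given in the sources used here. The title of the series asks whether fetal liver endothelial progenitors need c-Maf to become zonated adult sinusoids, the fenestrated capillaries of the liver. The control table held 9038 barcodes with 54143192 UMIs, and that of the c-Maf KO library 9058 barcodes with 60281713 UMIs. The authors' annotation kept 7669 and 8166 cells, of which 2948 and 2991 were endothelial and 4599 and 5085 hematopoietic. Endothelial cells were deeper in the c-Maf KO library, with a median of 7320 UMIs against 4985.5, and held 22621086 UMIs in sum against 16238502. With 1 library per group no difference has a replicate check, every comparison is between these 2 libraries, and every 95% interval covers counting error only.

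Maf, which encodes the basic leucine zipper transcription factor c-Maf, fell in endothelial cells of the c-Maf KO library. Its level went from 2070 to 162 CPM (counts scaled to the total of endothelial UMIs), a log2 ratio of -3.68 (95% interval -3.73 to -3.63). A Maf UMI was present in 89.0% of control and 14.3% of c-Maf KO endothelial cells. In B lineage cells, taken as background, the shares were 7.91% and 4.91% at median depths of 3662.5 and 2990 UMIs, and the levels were 22.0 and 18.4 CPM. Most of the Maf left in the c-Maf KO library lay in the authors' clusters S and S2, the clusters that held most control endothelial cells. These clusters held 336 c-Maf KO cells and 3316 of the 3658 Maf UMIs of c-Maf KO endothelial cells. Their Maf level was 1732 CPM (1673 to 1792), close to the 2158 CPM of control cells in the same clusters. The other 2655 c-Maf KO endothelial cells had 16.5 CPM of Maf (14.8 to 18.4), against 890.5 CPM in the 169 control endothelial cells outside S and S2. Cells with a UMI of Xist and none of 4 Y-linked genes (female-type) had a ratio of -3.18, and cells with a Y-linked UMI and none of Xist (male-type) one of -9.06. The mix of these types differed between the libraries. Among endothelial cells with at least 1128 UMIs, 760 control cells were female-type and 825 male-type, against 1677 and 321 c-Maf KO cells. Maf lies on chromosome 8 from 115682942 to 115707794 on the minus strand (GRCm38, GENCODE M21), and the last exon of its transcript Maf-201, from 115682942 to 115684761, is 3′ untranslated. Which part of the gene the allele deletes is not given in the sources used here. Tags from outside a deleted part would still be counted.

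**Figure D1:**
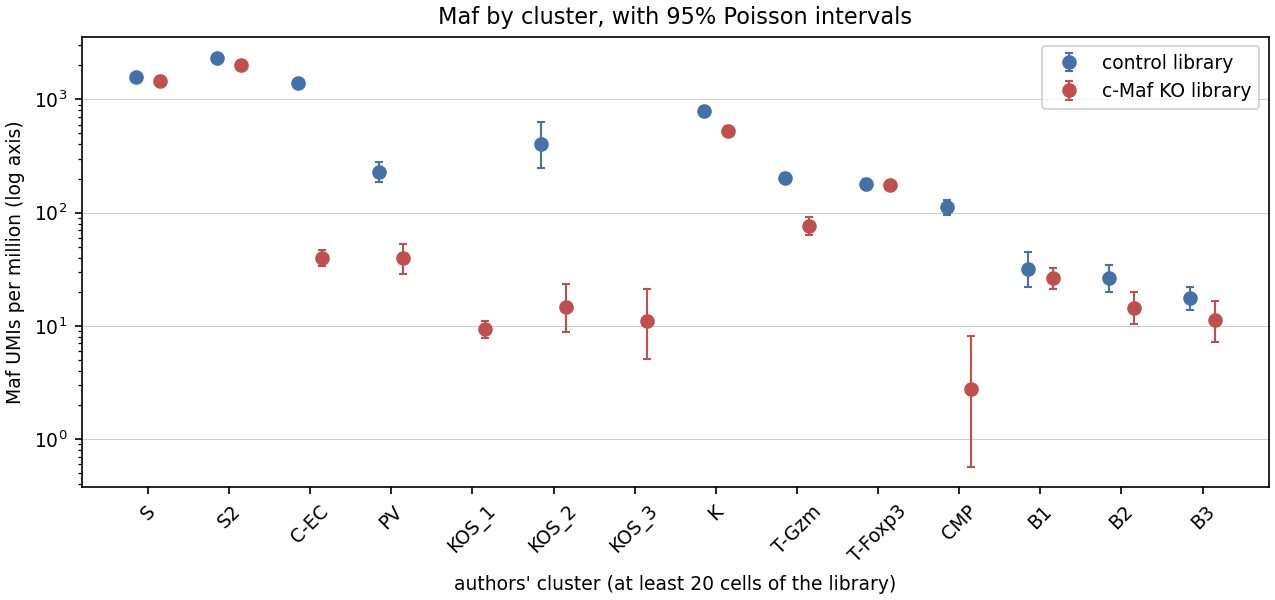
Maf in CPM (log axis) in the endothelial and some hematopoietic clusters of the authors, shown where a library had at least 20 cells; bars are exact Poisson 95% intervals. In the c-Maf KO library Maf stood at 1457 CPM in cluster S and 1998 in S2, and at 9.32, 14.8 and 11.1 CPM in KOS_1, KOS_2 and KOS_3.

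Genes that mark the liver sinusoidal endothelium were lower as a group in the c-Maf KO library. A gene was called higher or lower when its levels differed by at least 1.5-fold, the interval of the ratio excluded equality and both sums together held at least 50 UMIs. Of 27 measured sinusoidal identity genes, 23 were lower, 1 was higher and 3 were neither. Dnase1l3, an extracellular DNase, fell from 2041 to 154 CPM (log2 ratio -3.73, -3.78 to -3.68). Aass, an enzyme of lysine degradation, fell from 107 to 13.8 CPM (-2.96, -3.14 to -2.78). The higher member was Pianp, at 1.48 and 10.8 CPM. The list's median log2 ratio was -1.64, below all 10000 random lists of matched expression. Scavenger and endocytic receptors were lower too, with 13 of 19 measured members lower, 1 higher and 5 neither, and a median of -1.40 at percentile 0. Stab2, the hyaluronan scavenger receptor stabilin-2, fell from 1617 to 259 CPM (-2.64, -2.68 to -2.60). Fcgr2b, an Fc receptor that clears immune complexes, fell from 1491 to 349 CPM, and the scavenger receptor Msr1 from 180.5 to 32.7. Cd36 and Scarb1 had log2 ratios of 0.25 and 0.15. The 2 lists share several members, among them Stab2 and Fcgr2b.

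Transcripts of other liver cells found in endothelial cells moved the same way as the sinusoidal genes. Hepatocyte transcripts had a median log2 ratio of -1.43 (percentile 0), with 14 of 20 lower, among them Trf and Fabp1, which went from 37.8 to 8.40 and from 42.9 to 11.8 CPM. Stellate and mesenchymal transcripts had a median of -1.30, with 8 of 14 lower, but 1 control cell held 128 of the 428 Dcn UMIs. Leukocyte transcripts had a median of -0.40 (percentile 0.36), and C1qb and C1qa, complement genes of Kupffer cells, went from 169 to 11.2 and from 60.1 to 6.06 CPM. Erythroid transcripts had a median of -0.60 over 8 genes, and Car2 went from 29.4 to 4.11 CPM. The erythroid median was 1.38 in female-type cells and -1.54 in male-type cells, and the stellate median was 0.00 under a stricter cell filter.

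Genes of the endothelium near the central vein were lower in the c-Maf KO library, with 11 of 18 measured members lower, 2 higher and 5 neither. Wnt2, a Wnt ligand that sinusoidal endothelium supplies to hepatocytes, fell from 370 to 49.2 CPM (-2.91, -3.01 to -2.82). Ackr4, an atypical chemokine receptor, fell from 25.4 to 3.32 CPM, and Dkk3, a secreted protein of the Dickkopf family, from 3.02 to 0.398. Ccnd1, the cyclin D1 gene, rose from 277 to 528 CPM, and Pcolce, an enhancer of procollagen processing, from 42.2 to 70.0. The median log2 ratio was -0.98 (percentile 0). It was -1.86 in sinusoidal cells alone, -1.25 in C-EC and -0.05 in PV, where it did not stand apart (percentile 28.8). Wnt ligands and signalling genes had a median of -0.83 (percentile 0), with 10 of 21 lower and 1 higher. Nkd1, an antagonist of Wnt signalling, fell from 34.4 to 12.2 CPM and Apcdd1, another Wnt inhibitor, rose from 1.17 to 7.65. The Wnt median was -0.31 without the cells richest in transcripts of other cell types, and -0.45 in male-type cells. Neither value stood apart from random lists.

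Periportal genes went both ways, with 4 of 18 higher, 4 lower and 10 neither, and a median of 0.09 at percentile 90.4. In large vessel cells (cluster PV) 6 were higher and 0 lower, with a median of 0.52 (percentile 100), and in cycling endothelial cells (C-EC) the median was 0.33 (percentile 99.9). Adgrg6, an adhesion G protein-coupled receptor, rose from 7.21 to 30.5 CPM. Adam23 fell from 607 to 206 and the endothelin receptor gene Ednrb from 563 to 272. Ednrb differed in female-type cells (-1.71) and had a log2 ratio of -0.02 in male-type cells.

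Several genes that were low in control endothelial cells were abundant in the c-Maf KO library. Ly6a, which encodes the surface antigen Sca-1, rose from 50.3 to 1876 CPM (5.22, 5.12 to 5.32). Pcp4l1 rose from 2.09 to 188.5 CPM (6.47, 6.01 to 7.02), and Pdlim3, a PDZ and LIM domain protein, from 1.66 to 115 (6.08, 5.56 to 6.71). Aplnr, the apelin receptor gene, rose from 10.8 to 165 CPM. Cd34, a sialomucin of continuous capillaries and progenitors, rose from 28.9 to 330 (3.51, 3.38 to 3.65), and Ly6c1 from 14.96 to 179.6. Of the 12 highest ratios, 3 rest on 1 control UMI each, so their folds are loose. Cd109 was 287-fold higher (51.2 at the lower bound), Chrm3 238-fold (42.4) and Plppr5 146-fold (26.0). Astn1, Mal, Gdf10, Ocln and Tro completed the 12 with Aplnr and had 4 to 15 control UMIs against 211 to 613 c-Maf KO UMIs. Ly6a and Ly6c1 belong to a gene family with near-identical copies, and how reads shared between them were counted is not given in the sources used here.

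The 12 lowest ratios included Maf and Dnase1l3. Cyp26b1, which degrades retinoic acid, fell from 205 to 16.3 CPM (-3.65, -3.81 to -3.50). Kcnj8, a potassium channel subunit, fell from 14.8 to 0.619 CPM and Tpbgl from 302 to 27.4. Il13ra2, Flrt1, Ptprd, Cyp7b1 and Enpp6 lay between -3.89 and -3.46. Mcpt4, a mast cell protease gene, had the lowest ratio (-7.00), but 211 of its 230 control UMIs came from 1 cell.

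**Figure D2:**
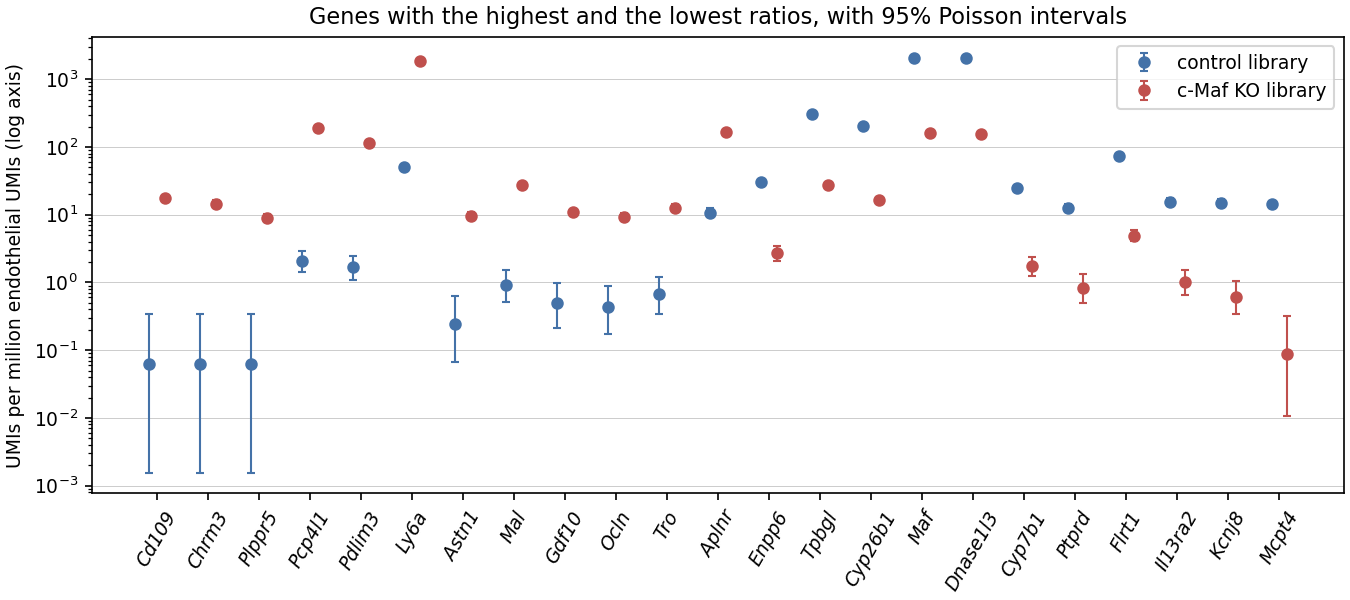
CPM of endothelial UMIs (log axis) for genes among the 12 with the highest and the 12 with the lowest log2 ratio at 200 UMIs or more (1 of the lowest is not shown), in the control and c-Maf KO libraries; bars are exact Poisson 95% intervals. Ly6a stands at 50.3 and 1876 CPM, and Dnase1l3 at 2041 and 154.

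The list of continuous capillary and capillarization genes went both ways. Of 26 measured members, 8 were higher, 7 lower and 11 neither, with a median log2 ratio of 0.09 (percentile 88.2). Beside Ly6a, Aplnr and Ly6c1, which rose, Tspan7 fell from 1016 to 194 CPM, Apln from 2.22 to 1.02 and Sparcl1 from 19.2 to 8.97. The median stood apart from random lists in sinusoidal cells alone (0.31, percentile 99.8), in C-EC (0.23, percentile 99.6) and, on the low side, in PV (-0.43, percentile 0). Arterial genes had a median of 0.07 (6 of 21 higher, 3 lower), with -0.07 in female-type cells, 0.80 in male-type cells and 0.75 in C-EC, the latter both at percentile 100. Venous genes had a median of -0.19 (6 of 17 higher, 6 lower). Clu, the chaperone clusterin, rose from 12.5 to 113 CPM, Vegfc, a growth factor of lymphatic and blood vessels, from 7.88 to 26.4, and Vwf, von Willebrand factor, from 41.6 to 96.8. Thbd, thrombomodulin, fell from 153 to 45.9 CPM, Nrp2, a semaphorin and VEGF co-receptor, from 433 to 170, and Selp, P-selectin, from 34.2 to 12.8. Tip cell and angiogenesis genes had a median of 0.04 (5 of 22 higher, 5 lower). Pdgfb, which recruits pericytes, rose from 3.88 to 35.7 CPM and Vegfa fell from 45.8 to 10.3.

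**Figure D3:**
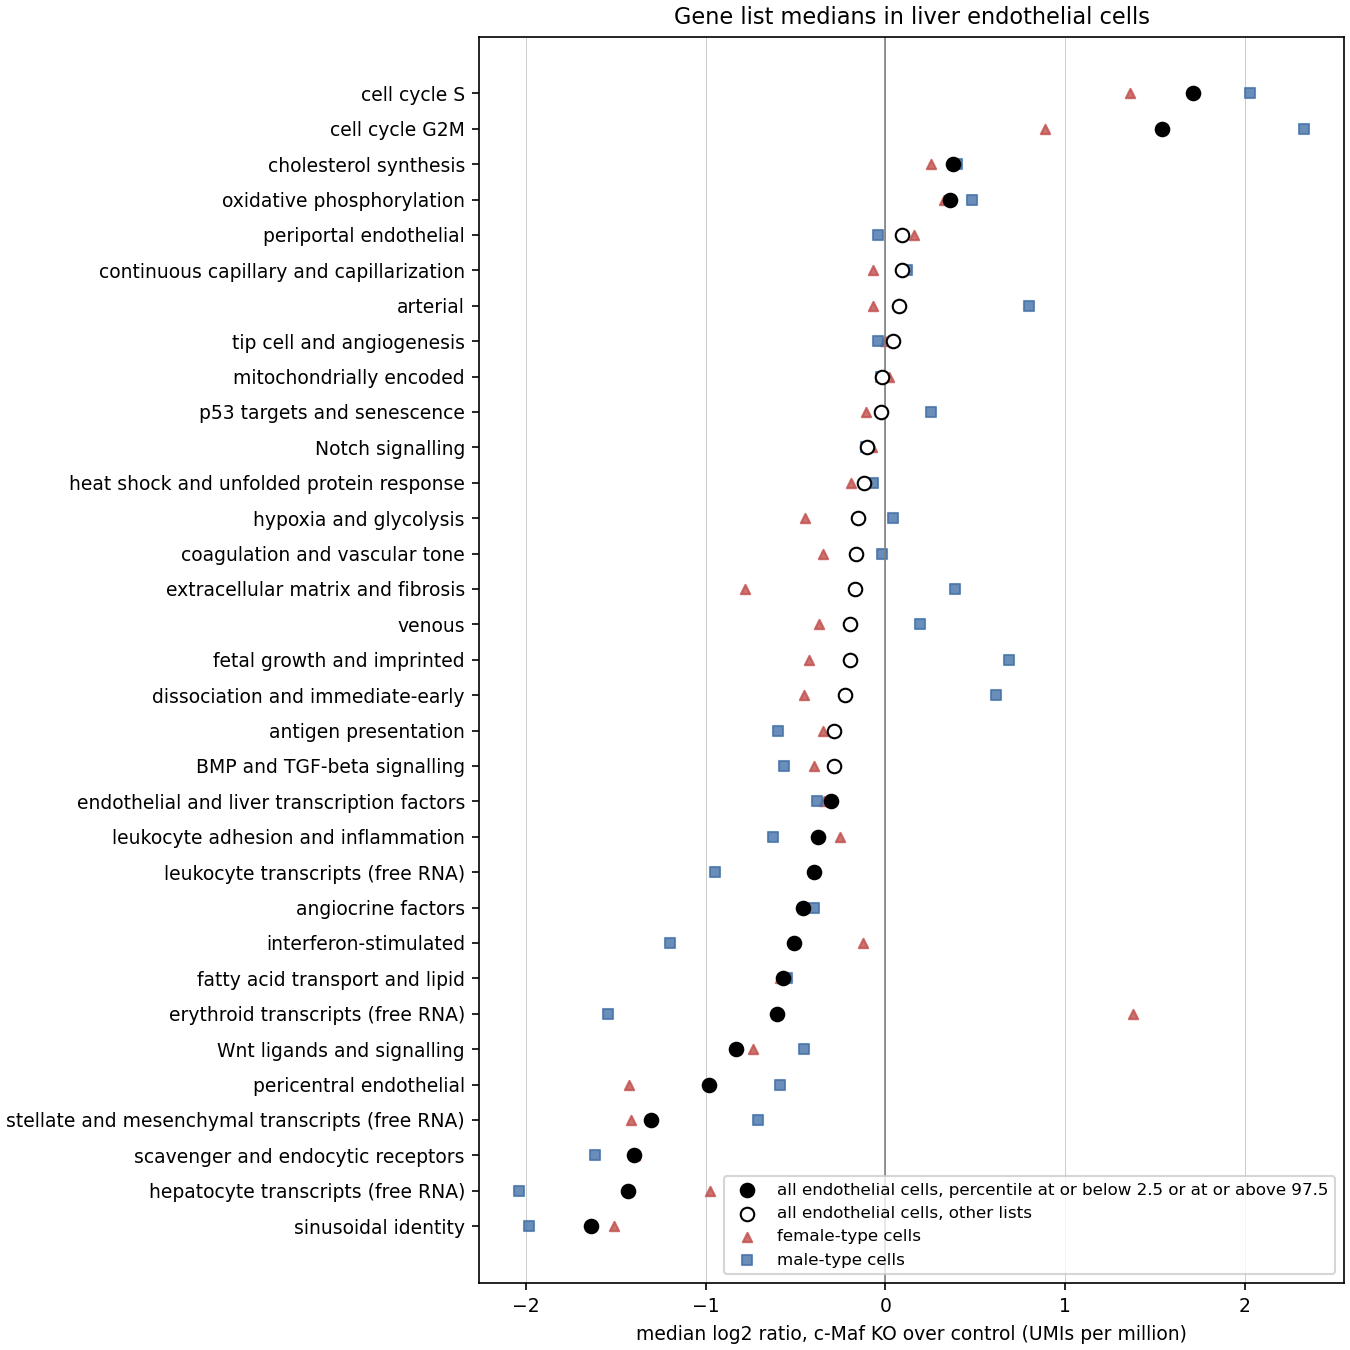
Median log2 ratio (c-Maf KO over control, CPM) of each of the 33 gene lists in all endothelial cells, female-type cells and male-type cells; filled circles mark medians that stand apart from matched random lists. In all endothelial cells sinusoidal identity lies lowest at -1.64 and the S phase list highest at 1.71.

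Cell cycle genes were higher in endothelial cells of the c-Maf KO library. Of 27 S phase genes, 26 were higher and Slbp was neither, and all 29 G2 and M phase genes were higher. Their median log2 ratios were 1.71 and 1.54, above all random lists. Hells, a helicase of replicating chromatin, rose from 9.18 to 58.1 CPM (2.66, 2.42 to 2.92), Uhrf1, which maintains DNA methylation, from 6.59 to 39.9, and Top2a, the topoisomerase of dividing cells, from 44.3 to 154 (1.80, 1.69 to 1.92). With each cell thinned to 1128 UMIs, a UMI of Mki67 or Top2a was found in 3.52% of 2585 control cells (2.84% to 4.30%) and 13.1% of 2760 c-Maf KO cells (11.8% to 14.4%). Thinning left out 363 and 231 shallower cells, and without it the shares were 6.72% and 26.3%. In B3, the B lineage cluster taken as background, the thinned shares were 0.963% and 3.13%. Without thinning they were 7.70% and 8.14%, at median depths of 4414 and 3612 UMIs. The control endothelial share without thinning was therefore not above this background. At equal depth it was, at 3.52% against 0.963% (0.417% to 1.89%). The thinned B3 share was itself higher in the c-Maf KO library (1.76% to 5.11%), on 8 control and 15 c-Maf KO cells with such a UMI. The thinned endothelial share was 5.26% and 13.3% in female-type cells and 1.09% and 12.8% in male-type cells. Without cells that carried a cycling marker both medians were 1.02, and both still stood apart from random lists. All 10 cycling markers belong to the G2 and M phase list, so the removal leaves them without UMIs and that median rests on the other members. With the control library's subtype mix applied to both libraries the S phase median was 1.35 and the G2 and M phase median 0.26 (percentile 99.7). Inside cluster C-EC the S phase median was -0.14 (percentile 55.9) and the G2 and M phase median -0.33 (percentile 0.38).

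Factors that endothelial cells secrete or present to their neighbours were lower as a group, with 12 of 28 angiocrine genes lower, 6 higher and a median of -0.46 (percentile 0.09). Igfbp7, an insulin-like growth factor binding protein, fell from 3915 to 1228 CPM (-1.67, -1.69 to -1.65), and the alarmin Il33 from 22.4 to 2.61 (-3.09, -3.53 to -2.70). Pdgfb and the Notch ligand gene Jag2 rose, Jag2 from 1.42 to 7.25 CPM. Igfbp5 rose from 29.3 to 76.3 CPM, but 1 control cell held 157 of its 476 UMIs and the female-type ratio was 0.06. In male-type cells the angiocrine median was -0.40 and did not stand apart.

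Transcription factors of endothelium and liver had 17 of 46 members lower, 2 higher and 27 neither, with a median of -0.30 (percentile 0.48). Mafg, which encodes a small Maf protein, fell from 137 to 43.8 CPM. Tcf15, a partner of Meox2 in heart capillaries, rose from 6.16 to 46.4 CPM (2.91, 2.62 to 3.22), and Mecom from 30.8 to 75.4. Genes of fatty acid transport and lipid handling had 9 of 19 lower, 3 higher and a median of -0.57 (percentile 0.07). Plin2, a lipid droplet protein, fell from 173 to 52.4 CPM and Lpl, lipoprotein lipase, from 9.55 to 4.02. Cholesterol synthesis genes had a median of 0.37 (percentile 99.2), with 4 of 19 higher and 0 lower. Sqle, squalene epoxidase, rose from 0.801 to 4.02 CPM, at low counts. The cholesterol list kept its call in 12 of 18 settings, and its medians of 0.25 in female-type and 0.40 in male-type cells did not stand apart. Oxidative phosphorylation genes had a median of 0.36 (percentile 99.8), yet 2 of 26 passed the size rule, Atp5g1 (0.76) and Atp5b (0.61).

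Interferon-stimulated genes had a median of -0.51 (percentile 0.01), with 11 of 27 lower and 1 higher. Ifi204 fell from 156 to 41.8 CPM, Ifit3 from 68.5 to 26.0 and Iigp1 from 297 to 125. In female-type cells alone the interferon median was -0.13, which did not stand apart. Leukocyte adhesion and inflammation genes had a median of -0.38 (percentile 1.05), with 8 of 19 lower. The chemokine scavenger receptor gene Ackr3 fell from 51.3 to 6.41 CPM (-3.00, -3.27 to -2.74) and Ccl2 from 5.48 to 1.15. The adhesion list kept its call in 13 of 18 settings, and did not stand apart with thinned cells (-0.34) or in female-type cells (-0.25). Vcam1 rose from 27.1 to 58.4 CPM, and Madcam1, which binds lymphocyte integrin, rose from 3 UMIs to 108, a ratio of 25.8 with a lower bound of 8.61.

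The other lists had medians that did not stand apart from random lists in all endothelial cells. BMP and TGF-beta signalling had a median of -0.29, with 7 of 22 lower, among them Tgfbr3 and Inhbb, and 2 higher, Bmper and Bmp6. It stood apart on the low side in female-type (-0.40), male-type (-0.56), sinusoidal (-0.43) and C-EC cells (-0.42), with 0.16 in PV. Notch signalling had one of -0.10, with Jag2 and Nrarp higher and Lfng and Dll1 lower. Coagulation and vascular tone went both ways, with 8 of 20 higher and 8 lower. In it Plat, tissue plasminogen activator, rose from 1.29 to 9.95 CPM and Tfpi, tissue factor pathway inhibitor, fell from 459 to 125. In the fetal growth list Mest rose from 235 to 1093 CPM (2.22, 2.17 to 2.27), Peg10 from 27.6 to 78.9 and Hmga2 from 24.1 to 67.2. Cdkn1c, a cyclin-dependent kinase inhibitor, fell from 87.0 to 44.1 CPM, and Dlk1 (67 control UMIs, 0 in the c-Maf KO library, at least 31.1-fold lower) had 50 of its UMIs in 1 cell. Extracellular matrix genes had a median of -0.17, with 6 of 36 higher and 11 lower. Ccn2, a matricellular target of YAP, rose from 4.99 to 35.3 CPM, while Loxl2 fell from 127 to 40.8 and Lgals1 from 356 to 119. The matrix median was 0.39 in male-type cells and the fetal growth median 0.69, both above random lists. Antigen presentation had a median of -0.29, and stood apart in female-type (-0.35, percentile 1.67) and male-type cells (-0.60, percentile 0.84). Medians were -0.02 for p53 targets, -0.15 for hypoxia and glycolysis, -0.12 for heat shock and unfolded protein response, -0.23 for immediate-early genes and -0.02 for mitochondrially encoded genes. Hypoxia and glycolysis (-0.45), coagulation (-0.35) and venous genes (-0.37) stood apart on the low side in female-type cells. Their male-type medians of 0.04, -0.02 and 0.19 did not stand apart. The mean lay above 0 for the venous, p53, heat shock and immediate-early lists, whose medians were below 0. Of the 33 lists, 17 stood apart, 13 low and 4 high. In simulated data with counting error only, 8% of lists made of unchanged genes fell outside the same percentiles.

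The shares of endothelial subtypes, grouped from the authors' clusters, also differed. Sinusoidal cells made up 95.1% of control (94.2% to 95.8%) and 81.8% of c-Maf KO endothelial cells (80.4% to 83.2%). This class rests partly on cluster names and does not show that its c-Maf KO cells kept sinusoidal expression. The sinusoidal identity median within it was -1.61 (percentile 0). In own clustering at resolution 1, the largest cluster of c-Maf KO cells (1325, with 0 control cells) scored highest for pan-endothelial markers. The largest of control cells (1797, with 247 c-Maf KO cells) scored highest for sinusoidal markers. Cycling endothelial cells (cluster C-EC) made up 3.02% (2.43% to 3.70%) and 13.6% (12.4% to 14.9%), and large vessel cells (PV) 1.90% (1.44% to 2.46%) and 4.51% (3.80% to 5.32%). Mest, which differed between the libraries, is among the leading genes of C-EC, so that its size is not independent of the change in expression. In female-type cells the PV shares were 5.31% and 5.14%, against 1.06% and 9.15% in male-type cells, and the C-EC shares 4.79% and 12.2%, against 1.18% and 13.1%. The sort can set the share of endothelial cells among all kept cells, which was 38.4% and 36.6%, and which went from 30.9% to 39.8% in female-type and from 41.2% to 22.5% in male-type cells.

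Sinusoidal cells came from different clusters in the 2 libraries, with 1320 control cells in S and 1459 in S2, and 1356, 518 and 238 c-Maf KO cells in KOS_1, KOS_2 and KOS_3. Pdlim3 had no UMI in control sinusoidal cells and 118 CPM in c-Maf KO cells, at least 596-fold higher against a floor of 3 control counts, and Pcp4l1 rose from 1.12 to 199.5 CPM. Ptprd fell from 12.5 to 0.556 CPM. Among the 10 leading genes of KOS_2, 2 are markers of megakaryocytes and 1 is endothelial. Without KOS_2 all 33 lists kept their calls. In cycling cells Ly6a rose from 6.27 to 1560 CPM and Maf fell from 1382 to 39.9, and the sinusoidal identity median was -1.68. In large vessel cells Ly6a rose from 949 to 3146 CPM, Atp13a3 from 85.2 to 284 and Pdlim3 from 62.2 to 208. Their sinusoidal identity median was -0.29 (percentile 0.03), with 7 genes higher and 9 lower. Their extracellular matrix median was -0.72 (percentile 0), and their stellate and mesenchymal transcripts moved alike, with a median of -0.85 (percentile 0.01). Mitochondrially encoded genes (-0.39, percentile 0.105) and immediate-early genes (-0.40, percentile 0) were lower in these cells as well. Ptn, Ccl21a and C3 were lower there but came from at most 8 cells of either library.

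Hematopoietic cells differed in make-up. Kupffer cells, the resident macrophages of the sinusoids, made up 16.7% of control (15.6% to 17.8%) and 3.80% of c-Maf KO hematopoietic cells (3.29% to 4.36%). B lineage cells made up 37.9% (36.5% to 39.3%) and 48.0% (46.7% to 49.4%), with cluster B1 at 6.41% and 21.9% and cluster B3 at 18.1% and 9.42%. Early B lineage cells of the cluster named CLP made up 1.20% (0.902% to 1.55%) and 4.70% (4.13% to 5.32%). T and NK cells made up 24.8% and 16.3%, and cycling hematopoietic cells (C1) 5.91% and 12.5%. Neutrophils made up 4.61% and 6.37%, monocytes 3.61% and 4.31%, dendritic cells 1.48% and 0.826%, plasmacytoid dendritic-like cells (CMP) 3.46% and 2.77%, and basophil-like cells 0.391% and 0.393%. The sort and cell capture can set these shares. In female-type cells neutrophils went the other way, from 4.14% to 3.54%, and Kupffer cells went from 6.03% to 1.99%. The C1 shares were 12.3% and 12.5% in female-type cells and 1.85% and 14.3% in male-type cells. T and NK cells were at 22.7% and 20.8% in female-type and 33.1% and 13.1% in male-type cells. The shares of CLP were 2.54% and 3.86% against 0.336% and 6.25%, and those of B1 12.7% and 17.6% against 2.43% and 28.1%.

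**Figure D4:**
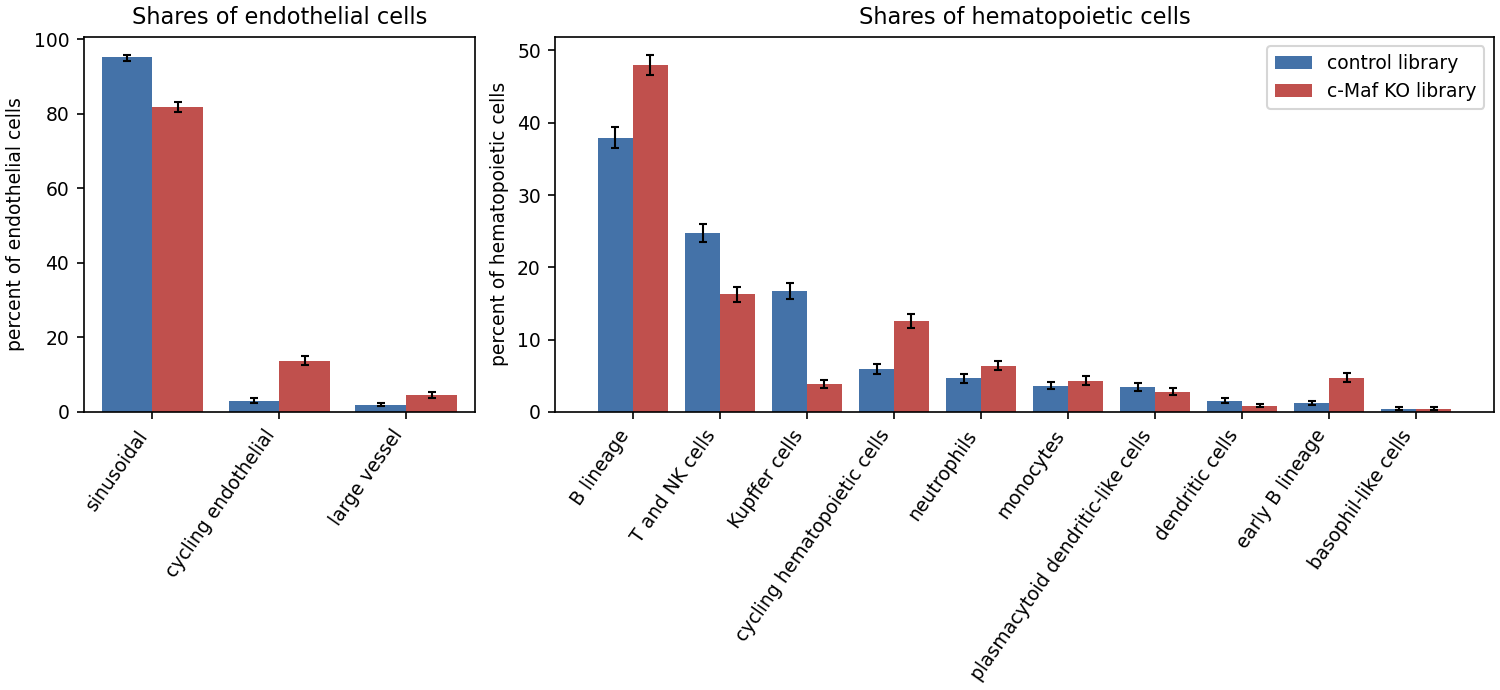
Percent of endothelial cells (left) and of hematopoietic cells (right) in each annotated class, for the control and c-Maf KO libraries; bars start at 0 and error bars are exact binomial 95% intervals. Kupffer cells stand at 16.7% and 3.80%, and cycling endothelial cells at 3.02% and 13.6%.

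Maf and sinusoidal transcripts were measured in 8 hematopoietic types as cells outside the endothelium. Maf was 797 and 529 CPM in Kupffer cells (log2 ratio -0.59, -0.73 to -0.45), 135 and 111 in T and NK cells (-0.28) and 22.0 and 18.4 in B lineage cells (-0.25). By B lineage cluster it was 32.0 and 26.5 in B1, 26.4 and 14.5 in B2 and 17.6 and 11.2 in B3. It was lower in early B lineage cells (137 and 86.5), monocytes (53.6 and 27.7), cycling hematopoietic cells (27.7 and 10.8) and neutrophils (55.5 and 10.95). In early B lineage cells 1 control cell held 17 of 46 Maf UMIs, and the ratio was -1.02 in female-type and 0.50 in male-type cells. In neutrophils it was -0.25 and -6.91. In the T cell cluster T-Foxp3 Maf was 181 and 174 CPM, and in T-Gzm 204 and 77.0. Plasmacytoid dendritic-like cells had 111 CPM of Maf in the control library (173 UMIs, 29 cells) and 2.77 in the c-Maf KO library (3 UMIs), a log2 ratio of -5.11 (-7.62 to -3.76). Outside the 5% of cells with the most sinusoidal transcripts, Maf was 31.2 and 3.03 CPM in these cells, and 82.8 and 109 CPM in T and NK cells, where it went the other way. The sinusoidal identity list was lower in all 8 types, with medians from -0.43 in monocytes to -2.66 in early B lineage cells, each at percentile 0. In Kupffer cells the lowest ratios were Slco2a1, a prostaglandin transporter (95.5 to 10.9 CPM), Dnase1l3 (294 to 38.0) and Flt4 (132.5 to 23.9). Dnase1l3 and Flt4 are on the sinusoidal list. In own clustering at resolution 2, Kupffer clusters with pan-endothelial scores of 3.03 and 2.09 held 64 and 53 control barcodes. They held 3 and 5 c-Maf KO barcodes, so droplets with endothelial RNA can enter these ratios. Kupffer cells were not part of the tests on shared droplets. Ltc4s, leukotriene C4 synthase, rose in Kupffer cells from 30.2 to 387 CPM, with UMIs in 36 control and 26 c-Maf KO cells. The chemokine gene Ccl9 rose from 29.5 to 241, in 39 and 28 cells. Their log2 ratios were 3.77 and 2.78 in female-type and 1.26 and 1.42 in male-type cells. Saa3 rose from 103 to 984 in few cells, 6 and 15, and had a ratio of -0.35 in male-type cells. Kupffer interferon-stimulated genes had a median of -0.76 (percentile 0) and immediate-early genes one of 0.38 (percentile 100), over 193 c-Maf KO cells. In the same cells erythroid transcripts had a median of -3.05, hepatocyte transcripts one of -0.77 and mitochondrially encoded genes one of -0.30, all at percentile 0.28 or below.

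For reference in GRCm38 with GENCODE M21, Dnase1l3 lies on chromosome 14 from 7964533 to 7994573, Stab2 on chromosome 10 from 86841198 to 87008025 and Wnt2 on chromosome 6 from 17988940 to 18030585. Ly6a lies on chromosome 15 from 74994877 to 74998031, Cd34 on chromosome 1 from 194938819 to 194961279, Pcp4l1 on chromosome 1 from 171173262 to 171196268 and Pdlim3 on chromosome 8 from 45885461 to 45919548. Top2a lies on chromosome 11 from 98992943 to 99024189 and Mest on chromosome 6 from 30723547 to 30748465.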

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

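Of the tests on the Maf left in the c-Maf KO library, those on free Maf RNA, on a mixture of both control mice and on Maf UMIs in shared barcodes were chosen only after the result was seen, as was the removal of S and S2. Free RNA spread over droplets does not account for it, as S and S2 held 90.7% of the Maf UMIs and 8.47% of all UMIs of c-Maf KO endothelial cells. Maf is among the leading genes of both clusters, so the size of this share is not independent of how cells were placed. A mixture of both control mice is not seen, as 0% of 247 sexed c-Maf KO cells of S and S2 were male-type (floor 1.21%), against 54.6% of control cells there and 18.5% of other c-Maf KO endothelial cells. Barcodes shared between the libraries made up 0.298% of these cells (upper limit 1.65%) and 0.339% of the others. As this limit lies above 0.339%, the share alone does not decide on carry-over from the control library. Cells with a shared barcode held 17 of the 3316 Maf UMIs of S and S2 (0.513%), too few to account for them. That value argues against Maf UMIs brought in under control barcodes as the source. Control cells mixed in before barcoding would carry new barcodes, so the value does not bear on them. The 0% of male-type cells argues only against a mixture of both control mice. Cells of the female control mouse alone, with 688 female-type control cells in S and S2, were not tested as a source and stay open. Cells of 1 mouse that kept Maf are a possible source, as all 247 sexed c-Maf KO cells of S and S2 were female-type. All 10 sexed C-EC and PV cells with at least 5 Maf UMIs were female-type too. With 19.9% of sexed cells of C-EC and PV male-type and a floor of 30%, the test on those 10 cells cannot decide.

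For the lower sinusoidal transcripts in hematopoietic cells the values outside the top 5% of cells were chosen only after the result was seen. Sinusoidal UMIs per cell differed 15.7-fold among 4 control types, beyond the bound set for free endothelial RNA at a like level in every droplet. Outside the top 5%, without plasmacytoid dendritic-like cells, they differed 2.21-fold. The rule took list UMIs as endothelial RNA, but list transcripts made by the hematopoietic cells themselves would also set types apart. In the c-Maf KO library the median was 14 list UMIs in plasmacytoid dendritic-like cells, 1 in B lineage, 1 in T and NK cells and 2 in neutrophils. The test therefore cannot exclude such free RNA. Free RNA in proportion to a droplet's UMIs was not tested and stays open, as B lineage, T and NK cells and neutrophils differed 1.32-fold in CPM. Endothelial cells sharing droplets with a few hematopoietic cells may account for part of it, as 5% of control B lineage, T and NK cells held 54.8% of these UMIs against 14.5% for an even spread at equal depth, with 69.5% against 9.39% in T and NK cells but 21.9% against 13.7% in B lineage cells. Outside the top 5% the c-Maf KO levels were still lower, at 313 and 224 CPM in T and NK cells, 392 and 286 in B lineage cells, 412 and 263 in neutrophils and 2273 and 1903 in plasmacytoid dendritic-like cells. Maf per sinusoidal UMI in plasmacytoid dendritic-like cells was 0.409 times that in endothelial cells, which leaves the source of their Maf open.

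For the 12 genes with the highest ratio the tests of subtype mix and of a small share of lung cells were chosen only after the result was seen, as were the 7 low-level lung genes, and the levels of Foxf1 were seen before the lung list was written. The genes were picked for their ratio in these same libraries, so their size is likely overstated, and the median was 5.16. It was 5.21 with the control library's subtype mix and 5.37 with cells thinned to the same number of UMIs. So neither depth nor the mix of sinusoidal, C-EC and PV cells accounts for it. A different mix within the sinusoidal class cannot be weighed this way, as most cells of the 2 libraries lie in different clusters there. Lung endothelial cells mixed into the c-Maf KO library do not account for it, as summed lung genes went from 752 to 180 CPM, a fold of 0.239 (0.231 to 0.248). Hpgd and Cyp4b1 dominate that sum and could hide a small share of lung cells, and among the 7 genes under 50 CPM, near the floor, Itga3 (1.17 to 2.52 CPM) and Prx (2.22 to 2.39) were higher, but in the 1317 c-Maf KO cells without a UMI of the 10 lung genes (median depth 3261 UMIs) the median was 5.18, so a small share does not account for it either.

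Opposite medians that stood apart in both female-type and male-type cells flagged 4 lists, and the difference was not tested. They were -0.42 and 0.69 for fetal growth, -0.78 and 0.39 for extracellular matrix, -0.45 and 0.61 for immediate-early genes and 1.38 and -1.54 for erythroid transcripts. Endothelial barcodes that the authors left out were flagged as unanalysed data, and the difference was not tested. Among those with 5000 genes or more, 72.2% of c-Maf KO and 36.8% of control barcodes had a UMI of Mki67 or Top2a, and among those with at least 20% mitochondrial UMIs 21.7% and 3.49%. These shares were not thinned, and the median depths of the latter barcodes were 1646 and 979 UMIs.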

How the results depend on the processing

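All log2 ratios are c-Maf KO over control, and shares are folds of c-Maf KO over control. Unless stated the alternatives were chosen before the data were examined. Of 2848 values for 178 named genes, 2629 stayed the same, 175 were weaker, 34 stronger and 10 reversed. Of 33 lists, 17 stood apart, 8 of them in all 18 settings. Maf was -3.55 with median of ratios scaling and -3.58 with TMM scaling. With equal weight per cell Maf was -3.23, the 12 lowest genes -3.39 and Lef1 reversed to -1.41. With thinned cells Maf was -3.28 and the 12 lowest genes -3.42. A stricter cell filter (554 control and 588 c-Maf KO endothelial cells) gave Maf -3.19, the 12 lowest genes -3.31, a continuous capillary median of 0.24 that stood apart and a reversed extracellular matrix median of 0.32. Its shares were 0.721 for endothelial cells, 3.41 for C-EC, 3.69 for PV, 0.816 for sinusoidal, 2.61 for B lineage, 0.381 for Kupffer and 0.573 for T and NK cells, and neutrophils reversed to 0.953. With own cell type calls Maf was -3.56, Lef1 reversed to -0.63 and the B lineage share was 1.40. In female-type cells Maf was -3.18 and the 12 highest genes 4.90. The erythroid median reversed to 1.38, as did Bmp4 to -1.09, Sele to -0.89, Hbb-bs to 1.45 and Hba-a2 to 1.38. Female-type shares reversed to 1.29 for endothelial cells, 0.968 for PV and 0.855 for neutrophils, and were 2.55 for C-EC, 0.919 for sinusoidal, 1.13 for B lineage, 0.330 for Kupffer and 0.916 for T and NK cells. In male-type cells Maf was -9.06 and the 12 lowest genes -5.31. Reversed male-type medians were 0.69 for fetal growth, 0.39 for extracellular matrix, 0.25 for p53 targets and 0.61 for immediate-early genes, and Cxcl12 reversed to 1.70. The Wnt median was weaker at -0.45 and the angiocrine median at -0.40. Male-type shares were 0.547 for endothelial cells, 11.1 for C-EC, 8.60 for PV, 0.795 for sinusoidal and 0.396 for T and NK cells. With the control library's subtype mix Maf was -3.50, the 12 lowest genes -3.67 and Bmp4 reversed to -0.70, and the G2 and M phase median went from 1.54 to 0.26. Without cells that carried a cycling marker Maf was -3.02, the 12 lowest genes -3.13 and the periportal median stronger at 0.15. The extracellular matrix median reversed there to 0.29, the erythroid median to 0.97, Hbb-bs to 1.32 and Hba-a2 to 1.09. With a pseudocount of 5 the 12 highest genes had a median of 4.56 and the 12 lowest -3.67. With list members of at least 200 UMIs the continuous capillary median was 0.24 and stood apart. Without the cells richest in other cells' transcripts (735 control and 428 c-Maf KO cells) the Wnt median was -0.31. Alternatives added after the data were seen left out c-Maf KO cells of S and S2 but no control cells, clusters with Maf among their leading genes, with Maf at -6.97 and the 12 lowest genes at -5.52, or KOS_2, with Maf at -3.61 and the sinusoidal share at 0.821. Leave-one-out was not possible, with 1 library per group. No paired analysis was possible because each group had 1 library and the labels name no shared animal, litter or batch. The female-type and male-type ratios and shares each set cells of 1 mouse against cells of 1 mouse. They cover only cells with a detected Xist or Y-linked UMI, which leaves out most shallow endothelial cells. For each of these shifts the cause was not tested.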

Other observations

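Some hematopoietic types differed in genes of their own. In B lineage cells Prg3 rose from 16.7 to 64.5 CPM and Gfra1 from 11.7 to 42.5, with cluster B1 giving 295 of 1744 control and 1114 of 2443 c-Maf KO cells of this class, so that its mix of clusters differed. The Prg3 log2 ratio was 0.47 in female-type cells and 4.58 in male-type cells. In the same cells the heat shock genes Hspa1a and Hspa1b, near-identical copies, fell from 193 to 55.5 and from 166 to 48.3, with ratios of -0.50 and -0.34 in female-type and -2.19 and -3.07 in male-type cells. In neutrophils Hspa1a and Hspa1b had log2 ratios of 2.59 and 2.83 in female-type cells and of -3.09 and -1.57 in male-type cells. Elane and Prtn3, protease genes of granulocyte precursors, rested on few neutrophils and also went opposite ways, at -1.99 and -2.13 in female-type and 1.72 and 5.97 in male-type cells. The G2 and M phase median was -0.83 in neutrophils and 0.74 in T and NK cells, where Eomes rose from 12.5 to 34.8 CPM. The mix of T and NK clusters differed too, with 444 and 210 cells in T-Cd6, 385 and 277 in T-Gzm and 310 and 340 in T-Foxp3. Jchain in B lineage cells, from 16.2 to 91.8 CPM, had 412 of 747 c-Maf KO UMIs in 1 cell.

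A few kept cells held many transcripts of a cell type other than that of their cluster. Sftpc, a surfactant gene of alveolar epithelium, had 3686 UMIs in 1 control cell and 2956 in 2 c-Maf KO cells of KOS_2, none with a UMI of 5 pan-endothelial genes (Pecam1, Cdh5, Kdr, Egfl7 and Ptprb). Mcpt4, a mast cell protease gene, had 211 UMIs in 1 control cell of KOS_2 and 404 in 1 c-Maf KO cell of the monocyte cluster, where the other mast cell list genes had 177 and 703 UMIs.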
